A study of Homo sapiens with 957 samples.

How the data were processed

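The series measured RNA in 957 human single cells, each prepared as 1 library with the SMART-Seq2 protocol, per the labels' protocols. The labels place 87 cells in the CD141+ cDC group, 77 in the CD1c+ cDC group, 341 in the Blood pre-cDC group and 452 in the CB pre-cDC group, where CB stands for cord blood. Conventional dendritic cells (cDC) present antigen to T cells, and pre-cDC are their circulating precursors. The CD141+ and CD1c+ cells are called mature cDC here, as the reference subsets for the precursors.

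Expression was quantified by the authors with RSEM 1.2.1 against the hg19 genome build, per the submitters' processing notes. The aligner and the gene annotation were not given in the sources used here. The deposited values were natural log values of a per-million amount plus 1, a reading taken from the values because no source used here names the unit or the log base. After the natural log was undone, the values of a cell summed to between 937914 and 1000001, with a median of 999892, over the 20689 entries of the table. Such near-constant sums are what a unit scaled to a fixed total per cell gives, and whether the unit was TPM or another of that kind was not settled. The values were undone to that amount and taken to log2 after a pseudocount of 1 was added, so that every level and difference is in log2 units. Such values keep no record of the sequencing depth of a cell, so the depth is unknown, and the number of genes above 0 in a cell (its detected genes) was used in its place.

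The lists, comparisons, score, clustering settings, filters, rule for naming genes and most other settings tried were chosen before the data were examined. That plan had expected linear values or log values used as deposited, and conversion from natural log to log2 changes only the scale. Before anything was computed, 43 genes were removed, because cells of a group can come from few people and such genes report on a person. These were the genes of the Y chromosome and of X inactivation, HLA-DRB3, HLA-DRB4 and HLA-DRB5, immunoglobulin and T cell receptor segments, and genes that people commonly lack. For the same reason no level is printed for the highly polymorphic genes HLA-C, HLA-DRB1, HLA-DPA1, HLA-DPB1, HLA-DQA1, HLA-DQA2 and HLA-DQB1, although the list medians include those that are list members.

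Cells needed at least 1000 detected genes, and 0 cells fell below this minimum. Genes above 0 in at least 10 cells were used, which kept 17661 genes and left out 2985. Among all entries of the table, 2195 were named only by a sequence accession, and these were passed over in naming. No doublet caller was run. No 2 cells had identical values, and the highest correlation between 2 cells was 0.874.

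No label names a donor or a preparation, so each group counted as 1 sample. No test was run between groups, and no standard error or count of changed genes was made from cells. A gene's level in a group is the mean over its cells with the SD over cells. Leading shares of cells are given with exact Clopper-Pearson 95% intervals and other shares without them. For most shares of 0, the limit that 3 cells would give is stated. These intervals and limits cover the counting of cells only, not differences between donors or preparations. The pre-cDC were set against mature cDC as the mean of the 2 precursor group means minus the mean of the 2 mature group means. A difference from that mean need not hold against each mature group.

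For each comparison and direction, the rule named the 12 genes with the largest difference that were above 0 in at least 25% of the cells of the higher group and kept their direction in both random parts of the cells. For pre-cDC against mature cDC, all 4 pairwise differences had to share a direction, and genes were ranked by the smallest of them. Pseudogenes, ribosomal protein genes, mitochondrial genes and unnamed entries were passed over. Any member of the lists could also be named. The 23 lists covered markers of CD141+ cDC, CD1c+ cDC, plasmacytoid dendritic cells (pDC) and AXL SIGLEC6 dendritic cells, B cell, T cell, NK cell and monocyte markers, and genes of progenitors, erythroid cells, platelets, and basophils and mast cells. They also covered genes of the cell cycle, MHC class II and antigen presentation, toll-like receptors, dendritic cell transcription factors, cytokine receptors, chemokine receptors and homing, interferon stimulation, immediate early and stress responses, glycolysis and oxidative phosphorylation, and fetal and oncofetal genes. JCHAIN, PKM2, ATP5F1A and ATP5F1B are other names of IGJ, PKM, ATP5A1 and ATP5B, under which the table holds these genes and they were analysed. H19, CD247, GZMA, FGFBP2, XCL1, ALAS2, AHSP and CA1 were not analysed here, since the table used held no entry under these symbols. For each list, the median difference was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Symbols are given as the table writes them, without coordinates.

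The subset score was derived on a random part of the mature cells, 43 CD141+ and 38 CD1c+, as the 30 genes per side with the largest difference of means that were above 0 in at least 50% of those cells of the higher group. A cell's score is the mean over the CD141+ side genes minus the mean over the CD1c+ side genes. The central 95% range of each mature group was taken on the other 44 CD141+ and 39 CD1c+ cells. Pre-cDC at or above the lower bound of the CD141+ range were counted in that range, those at or below the upper bound of the CD1c+ range in the other, and the rest as between. Clusters were found within each pre-cDC group alone with the Leiden method on 2000 variable genes, 20 principal components and 15 neighbours at a resolution of 0.5 and seed 0.

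After the values were seen, a set of pre-cDC libraries was found that carried transcripts of foreign tissues. A library was placed in this set when at least 2 of 6 panel genes (APOA2, TFF1, DCT, APOA1, FABP1 and PRSS2) were above 0. The panel was chosen from the values, and APOA2, TFF1 and DCT of the panel are also among the genes named in a comparison. Values outside and in the set stand beside the pooled values. Settings added then used the libraries outside the set, those in the set, those with 0 of the 6 genes, and a score without small RNA and unnamed entries.

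The steps were tested on simulated data before use. Each simulation divided the cells of a single group at random and raised genes in a random part of them. The group was Blood pre-cDC for CB against Blood pre-cDC, CD141+ cDC for CD141+ against CD1c+ cDC, and CB pre-cDC for pre-cDC against mature cDC. The spread of unchanged genes below therefore covers random division of a group, not differences between groups. For CB against Blood pre-cDC, over 3664 genes, those raised 4-fold had a true median difference of 0.78 and a recovered one of 0.82, and those raised 2-fold 0.40 and 0.46. Unchanged genes there had a median of 0.03, and 95% of them stayed within 0.61. For CD141+ against CD1c+ cDC, over 3698 genes, 4-fold genes gave 0.91 true and 1.02 recovered, 2-fold genes gave 0.39 and 0.46, and 95% of unchanged genes stayed within 1.02. For pre-cDC against mature cDC, over 6179 genes, 4-fold genes gave 0.90 and 0.95, 2-fold genes gave 0.38 and 0.46, and 95% of unchanged genes stayed within 0.44. A planted list reached percentile 100 in each comparison. Of 200 unchanged lists, 3.5%, 11.5% and 2% fell outside percentiles 2.5 to 97.5 in these comparisons, in the same order, where 5% is the nominal share. Of 200 simulated mixtures of a CD141+ and a CD1c+ cell, 64.5% scored between the ranges.

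The other settings chosen in advance changed the pseudocount to 0.1 or 10, the mean of log values to the log of linear means, the minimum to 2000 detected genes, the gene filter, the cells used (matched on detected genes in bins of 500, or a random part), the scaling (by 487 genes above 0 in at least 80% of cells), the level that counts as detected, and the settings of the score and clusters. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9.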

Results

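The labels describe 957 libraries of 1 cell each, from 87 CD141+ cDC, 77 CD1c+ cDC, 341 Blood pre-cDC and 452 CB pre-cDC, and the table gave 20689 entries per cell. Mature CD141+ cDC had a median of 2892 detected genes per cell (range 1079 to 5026) and CD1c+ cDC had 3576 (1074 to 5309). Blood pre-cDC had 2638 (1035 to 5844) and CB pre-cDC had 3884 (1003 to 8031). Ribosomal protein genes took 35.4% of the values in CD141+ cDC, 29.3% in CD1c+ cDC, 27.5% in Blood pre-cDC and 30.2% in CB pre-cDC. B2M, a subunit of MHC class I molecules, was above 0 in 99.7% of Blood pre-cDC and 100% of the cells of each other group.

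Both precursor groups contained libraries with transcripts that dendritic cells are not known to make. At least 2 of the genes APOA2, TFF1, DCT, APOA1, FABP1 and PRSS2 were above 0 in 42.5% of 341 Blood pre-cDC (interval 37.2% to 47.96%) and in 32.96% of 452 CB pre-cDC (28.6% to 37.5%). No mature cDC met this rule, with 0 of 87 CD141+ cells, which allows up to 3.45%, and 0 of 77 CD1c+ cells, which allows up to 3.90%. These libraries, called the foreign-transcript set from here on, had a median of 4070 detected genes in Blood pre-cDC, against 1976 outside the set. In CB pre-cDC the order was the opposite, with 3557 in the set and 4490 outside it. Because the set divides both precursor groups, each comparison that involves pre-cDC is given for all cells, outside the set and in the set. Where 2 values follow in brackets in such a comparison, the first is for cells outside the set and the second for cells in it.

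The mature subsets were compared first, to establish the reference against which precursors can be read. CD141+ cDC, the subset specialised in cross-presentation, had far higher levels of CLEC9A, a receptor for dead cells, at 7.86 ± 2.39 (SD, 87 cells) against 0.16 ± 1.16 in CD1c+ cDC (77 cells). CLEC9A was above 0 in 95.4% of CD141+ and 2.60% of CD1c+ cells. C1ORF54 averaged 11.78 ± 1.81 against 2.33 ± 3.69, IDO1, an enzyme of tryptophan breakdown, 8.16 ± 2.48 against 0.82 ± 1.86, and the nuclease gene DNASE1L3 7.68 ± 3.81 against 0.52 ± 1.71. In the opposite direction, the high-affinity IgE receptor gene FCER1A averaged 1.04 ± 2.12 in CD141+ and 11.30 ± 2.28 in CD1c+ cDC. The lipid-presenting molecule CD1C, used to name the other subset, was above 0 in 11.5% of CD141+ and 90.9% of CD1c+ cells, with a difference of -6.37.

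All 22 measured CD141+ cDC markers were higher in CD141+ cDC, 18 of them by at least 1, with a median difference of 2.54 at percentile 100 of matched random lists. Beyond the genes above, CPNE3 differed by 4.71, the adhesion gene CADM1 by 4.27, the transcription factor IRF8 by 4.16, CAMK2D by 4.09 and CLNK by 3.64. The transcription factors BATF3 and ID2 differed by 2.61 and 1.58, and the chemokine receptor XCR1 by 1.44. The naming rule also took TMEM14A at 4.99, RGCC at 4.25 and SLAMF7, with means of 4.54 and 0.54. Among 22 CD1c+ cDC markers, 21 were lower in CD141+ cDC, 18 of them by at least 1, with a median of -2.47 at percentile 0. CLEC4A differed by -5.96, CLEC10A by -4.16, ZEB2 by -3.74, CD33 by -3.72 and both IRF4 and KLF4 by -1.90. CLEC7A, the receptor for beta-glucan, was the exception among these markers at 0.86.

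Monocyte markers, interferon-stimulated genes and immediate early genes were lower in CD141+ cDC. All 12 monocyte markers were lower, 6 of them by at least 1, with a median of -1.31 at percentile 0. S100A9 differed by -2.95, S100A8 by -2.92 and the scavenger receptor CD36 by -2.77. The signalling adaptor TYROBP differed by -8.06, S100A4 by -7.77, IGSF6 by -7.10, the inflammatory protease CASP1 by -6.86, CARD16 by -6.54, CSTA by -6.39 and IFI30 by -6.07. RN7SL1 and RN7SL2, small RNAs of the signal recognition particle that lack a long poly(A) tail, differed by -8.03 and -7.11. Of 18 interferon-stimulated genes, 15 were lower in CD141+ cDC, with a median of -0.36 at percentile 0.430 and examples in XAF1 at -2.38 and OAS1 at -2.03. Of 15 immediate early and stress genes, 13 were lower, with a median of -0.44 at percentile 2.44, among them ZFP36 at -2.96, JUNB at -2.44, FOS at -2.37 and DUSP1 at -2.33.

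The receptor, metabolic and other lists had medians between -0.65 and 0.12 for these subsets. Of 11 cytokine receptor genes, 9 were lower in CD141+ cDC, with a median of -0.65 at percentile 1.56. The chemokine receptor and homing list had a median of -0.25 at percentile 20.9, with CXCR4 at -3.54. Toll-like receptor genes were divided 6 and 6, with TLR2 at -2.20 and TLR10 at 1.11. The MHC class II and antigen presentation list had 9 genes higher and 8 lower and a median of 0.05 at percentile 98.6. HLA-DRA averaged 14.28 ± 0.91 in CD141+ and 13.77 ± 0.93 in CD1c+ cDC. The pDC markers had a median of -0.27, although SERPINF1 differed by 2.94 and CLEC4C by 1.61. Transcription factors had a median of -0.27, glycolysis genes -0.38 at percentile 21.8, oxidative phosphorylation genes -0.26 at percentile 78.8, and progenitor and cell cycle genes 0.12 each, at percentiles 99.95 and 99.98. The remaining lists had medians of -0.19 for AXL SIGLEC6 dendritic cell markers, -0.12 for B cell markers, 0.00 for T cell markers, -0.07 for NK cell markers, -0.05 for erythroid genes, -0.03 for platelet genes, -0.01 for basophil and mast cell genes and -0.12 for fetal and oncofetal genes. Each mature group counted as 1 sample, so these differences have no replicate check, and the median over all genes was -0.06.

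**Figure D1:**
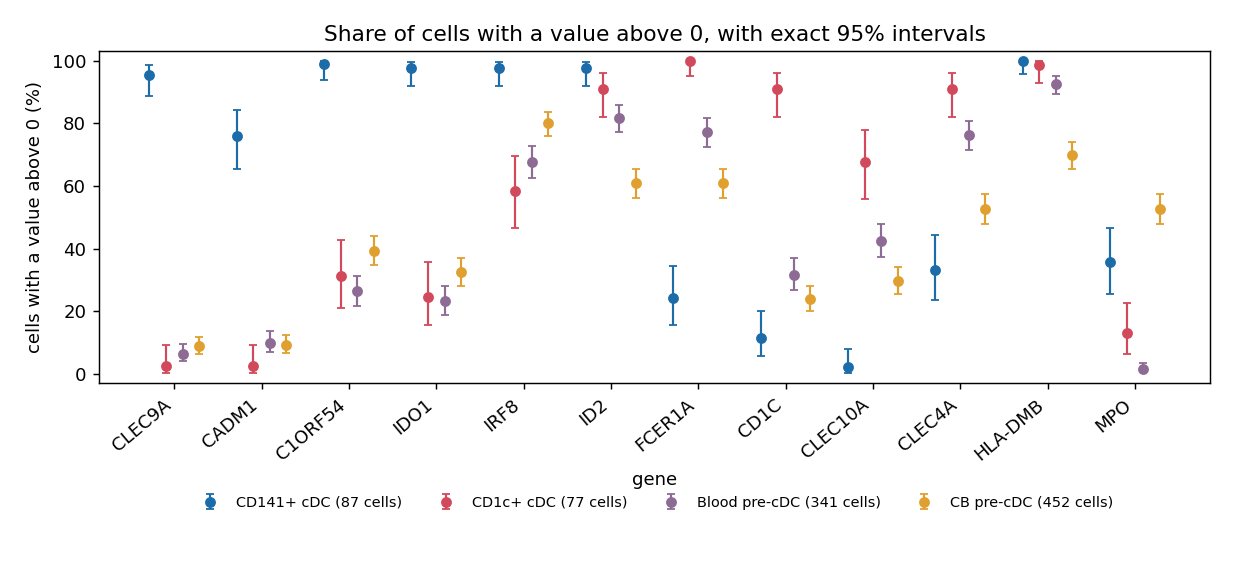
Share of cells with a value above 0 (percent, vertical axis) for 12 genes in the 4 groups, with exact 95% intervals that cover the counting of cells only. CLEC9A was above 0 in 95.4% of CD141+ cDC and in under 10% of the cells of the other groups, and MPO in 52.7% of CB pre-cDC.

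The next comparison asked how the precursors differ from the mature subsets. The interferon-induced antiviral gene IFITM3 was higher in pre-cDC by 4.89, with means of 6.62 ± 3.39 in Blood pre-cDC (341 cells) and 6.03 ± 3.05 in CB pre-cDC (452 cells) against 0.45 ± 1.46 in CD141+ and 2.44 ± 3.53 in CD1c+ cDC. The difference was 4.32 outside the foreign-transcript set and 5.99 in it. The galectin gene LGALS2 was lower in pre-cDC, with a difference of -4.81 (-4.72 outside the set and -4.87 in it), as were FAM26F at -4.28 (-4.35 and -4.20) and the carboxypeptidase CPVL at -3.61 (-3.24 and -4.33). CLEC7A, a CD1c+ marker that both mature subsets carried, had a difference of -3.26 (-3.39 and -3.06).

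Genes of the cell cycle were higher in pre-cDC in all 28 cases, 7 of them by at least 1, with a median difference of 0.63 at percentile 100. The median was 0.53 outside the set, where 28 genes were also higher and 3 of them by at least 1, and 0.70 in the set. By group, the median difference from mature cDC was 0.21 in Blood pre-cDC (-0.07 and 0.67) and 1.09 in CB pre-cDC (1.06 and 0.73), so outside the set the higher level lay in CB pre-cDC alone. MCM6, a part of the replicative helicase, was higher by 1.53 (1.17 outside the set and 2.04 in it), MCM3 by 1.13 (1.23 and 0.84) and the thymidylate synthase gene TYMS by 1.11 (1.13 and 0.96). TOP2A, a topoisomerase of dividing cells, was above 0 in 1.02% of Blood pre-cDC outside the set and 51.7% in it, and in 17.8% and 67.1% of CB pre-cDC. Immediate early and stress genes were higher in 13 of 15 cases, 6 of them by at least 1, with a median of 0.63 that was 0.88 outside the set and 0.51 in it, and by group it was 0.34 in Blood (0.07 and 0.35) and 1.38 in CB pre-cDC (1.73 and 0.61). JUNB differed by 2.17 (1.81 and 2.70), FOS by 1.51 (2.07 and 0.52) and the nuclear receptor NR4A1 by 1.51 (1.22 and 1.92). Progenitor genes were higher in 13 of 18 cases with a median of 0.32, which was 0.39 outside the set, -0.09 in it and 0.19 among cells matched on detected genes. By group it was -0.16 in Blood (-0.32 and -0.07) and 0.79 in CB pre-cDC (1.05 and -0.08), so the list was not higher in Blood pre-cDC. MPO, a progenitor gene, was above 0 in 52.7% of CB pre-cDC and 1.47% of Blood pre-cDC.

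MHC class II and antigen presentation genes were lower in pre-cDC in 14 of 17 cases, 8 of them by at least 1, with a median of -0.75 (-0.70 outside the set and -0.84 in it) at percentile 0.010. The lower level lay mainly in CB pre-cDC, with a median of -1.64 (-1.89 and -1.29) against -0.35 in Blood pre-cDC (-0.00 and -0.49). HLA-DRA differed by -1.77 (-1.91 and -1.48), HLA-DMB by -1.77 (-1.66 and -1.96), HLA-DMA by -1.33 (-1.05 and -1.75) and the invariant chain CD74 by -1.13 (-1.06 and -1.17). The lysosomal reductase IFI30 was higher than the mean of the mature groups by 1.87 (1.37 and 2.77). IFI30 was far lower in CD141+ than in CD1c+ cDC, so this does not place the pre-cDC above both mature subsets. All 22 CD141+ cDC markers were lower in pre-cDC, 14 of them by at least 1, with a median of -1.52 (-1.54 and -1.49). This follows in part from how the mean of the mature groups was built, because CLEC9A at 0.48 ± 1.88 in Blood and 0.53 ± 1.88 in CB pre-cDC was above the 0.16 ± 1.16 of CD1c+ cDC and below the 7.86 ± 2.39 of CD141+ cDC. ID2, BATF3 and the myeloid regulator SPI1 were lower, with differences of -3.08 (-3.04 and -3.14), -2.09 (-1.94 and -2.27) and -1.14 (-0.95 and -1.58). TCF4 and ZEB2 were higher by 1.05 (0.72 and 1.59) and 1.15 (1.38 and 0.52), and the transcription factor list had a median of 0.03 (-0.00 and -0.06). ZEB2, like IFI30, was lower in CD141+ than in CD1c+ cDC, so its value does not place the pre-cDC above both.

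The other lists had medians between -0.28 and 0.40, where the median over all genes was 0.05. CD1c+ cDC markers had a median of 0.09 (0.12 outside the set and -0.13 in it), pDC markers 0.23 (0.10 and 0.20) and AXL SIGLEC6 dendritic cell markers 0.09 (0.09 and 0.09). Toll-like receptor genes had a median of -0.28 (-0.15 and -0.34) at percentile 0, with the adaptor MYD88 at -1.63 (-1.49 and -1.96). The chemokine receptor and homing list had a median of 0.16 (0.12 and 0.08), with CXCR4 at 1.70 (1.28 and 2.25) and ITGB2 at 1.37 (1.28 and 1.41). CXCR4 was lower in CD141+ than in CD1c+ cDC, so its value does not place the pre-cDC above both. Cytokine receptor genes had a median of -0.04 (0.06 and -0.20), with IFNGR1 at -1.64 (-1.60 and -1.75) and FLT3 at -0.86 (-0.85 and -0.93). Interferon-stimulated genes had a median of 0.17 (0.21 and 0.06), monocyte markers 0.20 (0.19 and -0.00), glycolysis genes 0.11 (0.25 and -0.11) and oxidative phosphorylation genes 0.05 (-0.24 and 0.27). Medians were 0.01 (-0.02 and 0.02) for B cell markers, 0.09 (0.01 and 0.13) for T cell markers, 0.07 (0.06 and 0.09) for NK cell markers, 0.07 (0.02 and 0.07) for platelet genes and 0.04 (0.02 and 0.05) for basophil and mast cell genes. Fetal and oncofetal genes had a median of 0.29 (0.25 and 0.32) and erythroid genes 0.40 (0.03 and 1.03), at percentiles 99.67 and 99.99. Outside the set these lists lay at percentiles 99.92 and 40.65.

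Other genes that the naming rule took as higher in pre-cDC had larger differences in the foreign-transcript set. APOA2, TFF1 and DCT help define the set, so their difference between its parts was fixed by the split. The small RNA gene BCYRN1 was higher by 5.47 over all cells, 0.97 outside the set and 12.97 in it. The apolipoprotein gene APOA2 gave 3.70, 0.10 and 9.74, and the fetal globin gene HBG1 gave 3.24, 0.21 and 8.35. TFF1, HBG2, HBE1, DCT, SNORD81 and GOT1 had differences between 1.90 and 2.78 over all cells and between 0.00 and 0.25 outside the set. RN7SK gave 2.00, 0.66 and 4.35, and TMEM107 gave 2.46, 1.24 and 4.42. When the rule was applied outside the set, it took IFITM3, RPN2 at 1.89 (1.12 in the set), UQCRC1 at 1.87 (0.30 in the set), TMBIM6 at 1.22 (1.17 in the set) and ATP6AP1 at 1.22 (0.91 in the set) among its 12 genes. Genes lower in pre-cDC were less tied to the set, as KIAA1598 differed by -3.30 (-3.31 and -3.37), ZFP36L1 by -2.25 (-2.37 and -2.06), HDAC9 by -2.18 (-2.10 and -2.41), IFT20 by -2.13 (-2.20 and -2.16), PPT1 by -1.85 (-1.59 and -2.47) and BRK1 by -1.80 (-2.00 and -1.61). ATP5D at -2.73 (-1.99 and -3.95) and MIR17HG at -2.90 (-2.33 and -4.05) completed the lower genes.

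The precursors of cord blood and blood were then compared with each other. Genes of neutrophil granules had the 4 largest differences among the named genes that were higher in CB pre-cDC, with MPO (myeloperoxidase) at 4.70 ± 5.51 in CB (452 cells) and 0.04 ± 0.39 in Blood pre-cDC (341 cells) and above 0 in 52.7% and 1.47% of cells. The difference for MPO was 4.65 over all cells, 6.90 outside the foreign-transcript set and 0.06 in it. The proteases PRTN3, ELANE and CTSG differed by 4.64 (6.91 and -0.00), 4.33 (6.27 and 0.39) and 4.17 (6.20 and 0.06). In the opposite direction, MHC class II genes were lower in CB pre-cDC outside and in the set. HLA-DRA averaged 10.96 ± 2.77 in CB and 13.54 ± 1.46 in Blood pre-cDC, a difference of -2.58 (-2.87 outside the set and -1.99 in it), and HLA-DMB 5.75 ± 4.26 and 8.89 ± 2.88, a difference of -3.15 (-3.16 and -3.20).

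Antigen presentation genes were lower in CB pre-cDC in 15 of 17 cases, 11 of them by at least 1, with a median of -1.79 at percentile 0. Outside the set the median was -2.11 and in it -1.42, again with 15 genes lower and 11 of them by at least 1. Outside the set, CB pre-cDC with at least 3 of MPO, ELANE, PRTN3, CTSG and AZU1 above 0 had a median of -3.04 against Blood pre-cDC, and those without -0.45, with HLA-DRA at -4.10 and -0.67 and CD74 at -3.04 and -0.45. That split was chosen after the values were seen. IFI30 differed by -3.38 (-3.69 and -2.50), the costimulatory gene CD86 by -2.31 (-2.83 and -1.42), the protease gene CTSH by -2.01 (-1.93 and -2.05) and CD74 by -1.56 (-2.11 and -0.68). The naming rule also took FGL2 at -3.20 (-3.05 and -3.48), TXNIP at -3.77 (-2.76 and -5.40), RGS2 at -3.07 (-3.56 and -2.38), FCER1A at -2.99 (-2.24 and -3.48) and AMICA1 at -2.91 (-3.28 and -2.16), and 5 polymorphic HLA genes whose levels are not given.

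Progenitor genes were higher in CB pre-cDC in 17 of 18 cases, 9 of them by at least 1, with a median of 0.83 at percentile 100. The median was 1.31 outside the set and 0.03 in it, where 1 gene was higher by at least 1, and 0.32 among cells matched on detected genes. MYB, a regulator of blood progenitors, differed by 1.55 (2.31 outside the set and 0.09 in it), CD38 by 1.37 (2.07 and -0.05) and SOX4 by 1.31 (1.94 and 1.11). The eosinophil granule ribonuclease genes RNASE2 and RNASE3 differed by 4.08 (6.04 and 0.19) and 3.27 (4.77 and 0.24), AZU1 by 3.18 (4.73 and 0.05), MS4A3 by 3.68 (5.41 and 0.20) and NUCB2 by 3.68 (5.69 and 0.44). NKG7, a lymphocyte granule gene, differed by 3.25 (4.99 and -0.02), and SNHG8 by 3.28 (5.16 and 0.88).

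Cell cycle genes were higher in CB pre-cDC in 27 of 28 cases, 11 of them by at least 1, with a median of 0.81 (1.17 outside the set and 0.19 in it), which was 0.28 among cells matched on detected genes. The division gene CKS2, which is not in the list, differed by 3.85 (5.70 and 1.29), and the list members STMN1 by 3.25 (5.40 and 0.71), TYMS by 1.81 (2.55 and 0.54) and MCM7 by 1.67 (2.58 and 0.04). In the set, 1 gene of the list was higher by at least 1. Immediate early and stress genes were higher in 14 of 15 cases, 7 of them by at least 1, with a median of 0.88 (1.12 and 0.09), which was 0.37 among matched cells. Glycolysis genes had a median of 0.63 (1.32 and -0.36), with GPI at 1.87 (2.97 and -0.21) and ENO1 at 1.28 (2.31 and -0.71). Oxidative phosphorylation genes had a median of 0.63 (1.15 and 0.07) at percentile 88.3, or 71.4 outside the set, within the range of random lists matched on expression. The chromatin gene HMGA1 and the RNA-binding gene IGF2BP3 differed by 1.91 (2.80 and 0.29) and 0.68 (1.01 and 0.12), in a fetal and oncofetal list with a median of 0.24 (0.42 and 0.26).

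**Figure D2:**
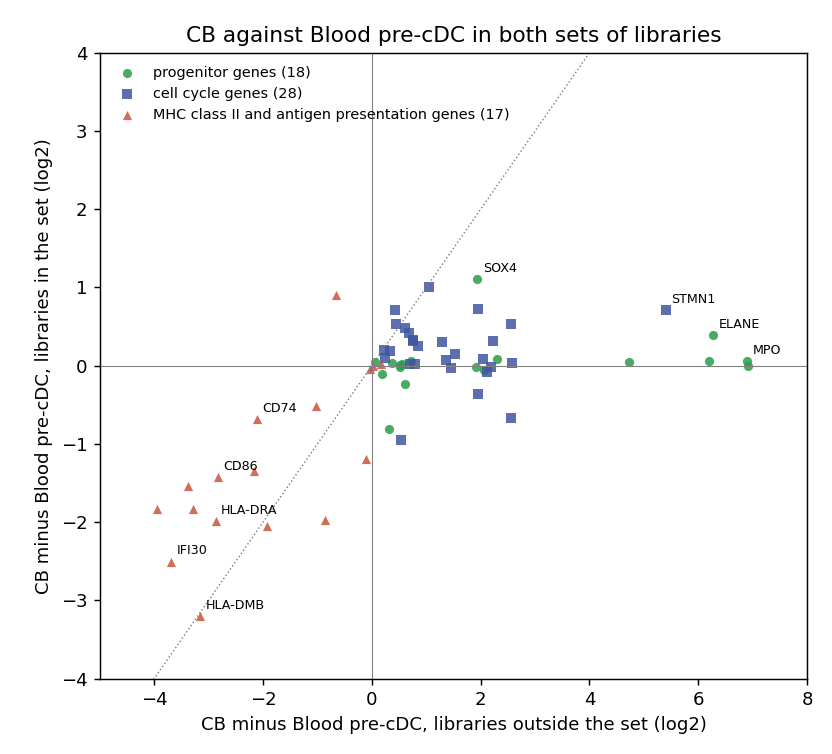
Difference between CB and Blood pre-cDC (log2 units) for each gene of 3 lists, outside the foreign-transcript set (horizontal axis) and in it (vertical axis), with the dotted line marking equal values. MPO lies at 6.90 and 0.06, whereas HLA-DMB lies at -3.16 and -3.20.

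Subset, signalling and lineage lists had medians between -0.44 and 0.17 over all cells of the precursor groups. CD141+ cDC markers had a median of -0.02 (-0.10 outside the set and -0.04 in it), with ID2 at -2.69 (-2.72 and -2.68). CD1c+ cDC markers had a median of -0.44 (-0.17 and -0.70) at percentile 0, with CLEC4A at -2.46 (-3.05 and -1.29). Interferon-stimulated genes were lower in 16 of 18 cases, with a median of -0.28 (-0.19 and -0.38) and the antiviral genes MX2 and MX1 at -1.42 (-1.19 and -1.86) and -1.05 (-1.37 and -0.61). Monocyte markers had a median of 0.05, which was 0.61 outside the set and -1.12 in it, and S100A9 went from 2.60 outside the set to -3.49 in it. ZEB2 and IRF8 went from 2.08 and 1.76 outside the set to -2.06 and -0.51 in it, in a transcription factor list with a median of -0.01 (0.19 and -0.58). Cytokine receptor genes had a median of 0.13 (0.31 and -0.73), and chemokine receptor and homing genes -0.01 (0.22 and -0.33). Toll-like receptor genes had a median of -0.09 (-0.05 and -0.22), pDC markers 0.13 (0.12 and 0.07) and AXL SIGLEC6 dendritic cell markers -0.04 (-0.06 and -0.10). Medians were 0.06 (0.07 and 0.01) for B cell markers, 0.06 (0.00 and 0.06) for T cell markers, 0.12 (0.17 and -0.01) for NK cell markers, 0.15 (0.22 and 0.33) for erythroid genes, 0.17 (0.32 and 0.04) for platelet genes and 0.12 (0.21 and -0.04) for basophil and mast cell genes. The median over all genes was 0.11 over all cells, 0.24 outside the set and -0.05 in it.

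The subset score asked whether single precursors resembled a mature subset. CD141+ cDC not used to derive the score had a median of 3.02 and CD1c+ cDC had -6.35, and the ranges were set on these same cells, so their share inside was fixed by construction. Blood pre-cDC had a median of -4.17 (-4.22 outside the set and -4.11 in it), and CB pre-cDC -3.23 (-3.23 and -3.20). Of Blood pre-cDC, 87.4% of 341 cells (interval 83.4% to 90.7%) scored in the CD1c+ range, 12 (3.52%, 1.83% to 6.07%) in the CD141+ range and 31 (9.09%, 6.26% to 12.7%) between them. Of CB pre-cDC, 63.3% of 452 cells (58.6% to 67.7%) scored in the CD1c+ range, 9 (1.99%, 0.914% to 3.75%) in the CD141+ range and 34.7% (30.3% to 39.3%) between. All 12 Blood pre-cDC in the CD141+ range lay outside the foreign-transcript set, where they made up 6.12% of cells, against 0 cells in the set, which allows up to 2.07%. The CD1c+ range held 81.6% of Blood pre-cDC outside the set and 95.2% in it, with 12.2% and 4.83% between the ranges, and 62.4% and 65.1% of CB pre-cDC, with 35.3% and 33.6% between. For CB pre-cDC the CD141+ range held 2.31% of cells outside the set and 1.34% in it. A range is not a cell type, and 21 Blood (6.16%) and 61 CB pre-cDC (13.5%) lay within 0.25 of a bound. The upper bound of the CD1c+ range rested on 2 of 39 CD1c+ cDC. The next of those cells scored -4.37, below the medians of both precursor groups, so the shares of both in and above that range depend on it.

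Levels of single genes were read in each score range. In the 12 Blood pre-cDC of the CD141+ range, medians over cells were 8.13 for CLEC9A, 9.73 for IRF8 and 10.67 for ID2, with CADM1 above 0 in 41.7% of the cells. In the 9 CB pre-cDC of that range, medians were 7.49 for CLEC9A, 10.52 for IRF8 and 9.55 for ID2, and MPO was above 0 in 33.3% of cells. CLEC9A, IRF8 and CADM1 belong to the score itself, whereas ID2, MPO and HLA-DRA do not. CB pre-cDC between the ranges had a median of 11.03 for MPO, which was above 0 in 63.1% of them, and a median of 9.73 for HLA-DRA. CB pre-cDC in the CD1c+ range had MPO above 0 in 47.6% of cells and a median of 12.41 for HLA-DRA. The share of precursors in the CD1c+ range moved with the settings of the score, from 28.4% to 93.5% for Blood and from 18.4% to 90.7% for CB pre-cDC.

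**Figure D3:**
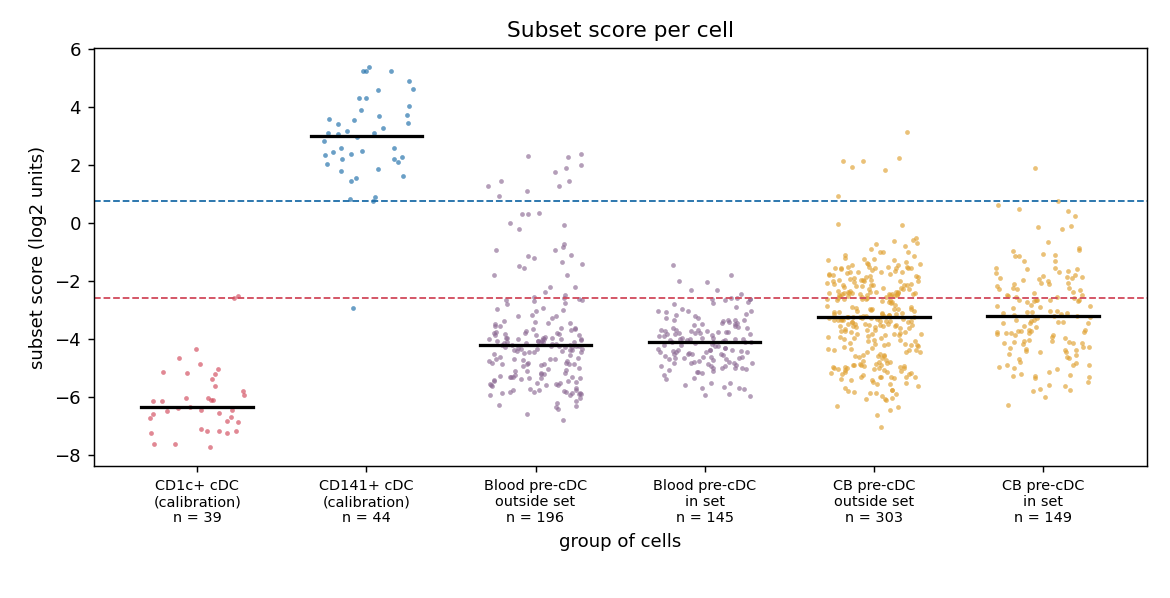
Subset score of each cell (log2 units, vertical axis) in the mature cells not used to derive it and in the pre-cDC groups, with the dashed lines at the bounds of the mature ranges, 0.75 and -2.58. Blood pre-cDC had a median of -4.17 and CB pre-cDC of -3.23.

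Co-detection of genes of opposite subsets asked whether precursors carried both programmes. CLEC9A and CD1C were both above 0 in 1 of 341 Blood pre-cDC (0.293%, interval 0.00742% to 1.62%), where the product of the single shares gives 2.04%, and in 8 of 452 CB pre-cDC (1.77%, 0.767% to 3.46%), where it gives 2.11%. Outside the set these shares were 0.510% and 2.31%, and in it 0 Blood pre-cDC, which allows up to 2.07%, and 0.671%. Mature CD141+ cDC had both genes in 10 of 87 cells (11.5%, 5.65% to 20.1%) and CD1c+ cDC in 2 of 77 (2.60%). CLEC9A and CLEC10A were both above 0 in 0.293% of Blood and 1.77% of CB pre-cDC, with products of 2.74% and 2.62%. Outside the set these shares were 0.510% and 1.32%, and in it 0 Blood pre-cDC, which allows up to 2.07%, and 2.68%. XCR1 and CD1C gave 0.587% and 0.442% with products of 0.464% and 0.264%, at 0.510% and 0.660% outside the set and 0.690% and 0 CB pre-cDC in it, which allows up to 2.01%. CADM1 and CD1C gave 2.64% and 2.21% with products of 3.16% and 2.22%. CADM1 and FCER1A were both above 0 in 7.92% of Blood and 6.86% of CB pre-cDC, with products of 7.72% and 5.65%. Both pairs with CADM1 depended on the set. CADM1 and CD1C were both above 0 in 0 Blood pre-cDC outside it, which allows up to 1.53%, and 6.21% in it, and in 0.990% and 4.70% of CB pre-cDC. CADM1 and FCER1A differed more, with 0 Blood pre-cDC outside it, which allows up to 1.53%, and 18.6% in it, and with 1.32% and 18.1% of CB pre-cDC. For that pair the products were 2.26% outside the set and 17.98% in it for Blood, and 2.05% and 15.9% for CB pre-cDC. For CADM1 and CD1C in the set they were 7.19% for Blood and 3.24% for CB pre-cDC. In the set each product lay within the exact interval of its share, so the rise there does not show more cells with both genes than the single shares give.

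Clustering within each group asked how heterogeneous the precursors were. Blood pre-cDC formed 3 clusters with 43.1%, 39.9% and 17.01% of the cells, and 95.9% of the largest were in the foreign-transcript set, against 2.21% of the next and 1.72% of the smallest, which held 58 cells. CB pre-cDC formed 6 clusters, of which the clusters of 85 and 64 cells lay wholly in the set and the other 4 wholly outside it. The clusters of 93 and 69 CB pre-cDC carried granule genes, since MPO, ELANE, PRTN3, CTSG and AZU1 were among the 10 leading genes of each. Between the score ranges lay 41.9% and 78.3% of their cells. The clusters of 87 and 54 cells gave 5.75% and 16.7%, and those of 85 and 64 cells in the set 20% and 51.6%. The median difference of the progenitor list from the other CB pre-cDC was 1.06 in the granule gene cluster of 93 cells and -0.01 in that of 69. The stem cell gene CD34 was above 0 in 1.08% of the first (interval 0.0272% to 5.85%) and in 0 of 69 cells of the other (up to 5.21%), with KIT in 41.9% and 15.9% and HLA-DRA in 96.8% and 97.1%. HLA-DRA averaged 9.02 ± 2.65 and 8.31 ± 2.77 in these clusters, against 13.25 ± 1.10 and 12.40 ± 2.16 in the clusters of 87 and 54 CB pre-cDC that also lay outside the set. FCER1A was above 0 in 21.5% and 28.99% of the granule gene clusters, against 87.4% and 75.9% in those of 87 and 54 cells. In the same order, CD1C gave 5.38% and 10.1% against 59.8% and 37.04%, and CLEC10A 3.23% and 4.35% against 49.4% and 53.7%. FLT3 did not divide them so, at 77.4% and 40.6% against 77.01% and 38.9%, nor did IRF8, at 88.2% and 71.01% against 97.7% and 70.4%. Differences of CB from Blood pre-cDC outside the set include cells of these granule gene clusters.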

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

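Every setting that uses the foreign-transcript set, its absence or a score without small RNA and unnamed entries was added after the data were seen, and the other settings were chosen before. A list median counted as the same within 1.5-fold and a share within its exact interval. Over the settings chosen in advance, 667 of 840 values were the same, 0 reversed and the others moved. Most of these values were for named genes, which were picked for large differences that kept their direction in both random parts of the cells. A random part was also one of the settings, so the count of 0 reversed says little for these genes. Among values not picked so, 26 of 48 score shares and 34 of 99 list medians moved. Fewer moved among list percentiles (1 of 99), cluster numbers (2 of 12) and co-detection shares (0 of 6). Over the added settings 71 values moved, 4 reversed and the others were the same. No paired analysis was possible because no source says that cells with the same number in different groups belong together, and no test was run. The setting without a filter on cells gave no value of its own, since no cell had fewer than 1000 detected genes. The sequencing depth of a cell is unknown, so a gene at 0 was not told apart from one missed, and the settings that bear on this were matching on detected genes, a minimum of 2000 of them, and higher detection levels for co-detection. Matching took no account of the foreign-transcript set, so matched Blood and CB pre-cDC can differ in their shares of it. The median over all genes for CB against Blood pre-cDC was 0.11, and it was 0.28 with a pseudocount of 0.1, 0.24 outside the set, 0.23 with none of the 6 genes, -0.05 in the set and -0.01 among matched cells. For pre-cDC against mature cDC it was 0.05, and 0.28 with linear means, and for CD141+ against CD1c+ cDC -0.06 and -0.21 with linear means. Where a value below moved or reversed, the cause was not tested, except that a pseudocount scales differences by its construction.

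For CD141+ against CD1c+ cDC, the CD141+ markers gave 4.08 with a pseudocount of 0.1 and 1.34 with 10, and the CD1c+ markers -1.30 with 10 and -3.85 with linear means. For pre-cDC against mature cDC, pseudocounts of 0.1 and 10 gave -2.45 and -0.73 for CD141+ markers, -1.15 and -0.33 for MHC class II genes, 0.55 and 0.14 for progenitor genes, 1.19 and 0.28 for cell cycle genes, and 1.19 and 0.38 for immediate early genes. Linear means gave -0.36 for MHC class II, 0.57 for progenitor, 1.39 for cell cycle and 1.58 for immediate early genes, and matched cells gave 0.19 for progenitor genes. In the set, the progenitor median reversed to -0.087, and with none of the 6 genes APOA2, one of them, reversed to -0.039.

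For CB against Blood pre-cDC, pseudocounts of 0.1 and 10 gave 1.53 and 0.29 for progenitor genes, 1.28 and 0.38 for cell cycle genes, and 1.54 and 0.41 for immediate early genes. Linear means gave -1.18 for MHC class II, 1.29 for progenitor and 1.34 for cell cycle genes. Without a gene filter the progenitor median was 0.43 and the immediate early median 0.58, and with at least 2000 detected genes the latter was 0.55. Among matched cells the progenitor, cell cycle and immediate early medians were 0.32, 0.28 and 0.37. In the set they were 0.028, 0.19 and 0.086, and the progenitor median was 1.31 both outside the set and with none of the 6 genes. In the set PRTN3 reversed to -0.0030 and NKG7 to -0.017.

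Of Blood pre-cDC, 80.1% scored in the CD1c+ range and 16.1% between with 60 genes per side, 81.5% and 14.4% with marker lists, 78.6% and 18.5% with the parts of the mature cells swapped, 65.98% and 30.5% with shares of genes detected, 91.6% and 4.64% with at least 2000 detected genes, 28.4% and 69.8% with the central 80% range, and 93.5% and 3.23% without small RNA and unnamed entries. In the same order, these shares of CB pre-cDC were 53.3% and 43.8%, 68.8% and 27.9%, 55.97% and 42.9%, 43.1% and 54.9%, 85.2% and 12.7%, 18.4% and 80.1%, and 90.7% and 6.42%. The share of Blood pre-cDC between was 12.9% without MHC class II, cell cycle, CD1C and THBD genes. In the CD1c+ range it was 81.6% outside the set and 95.2% in it, with 4.83% between in the set. In the CD141+ range it was 1.76% with the 80% range, 6.12% outside the set and 0% in it, while for CB pre-cDC the CD141+ share stayed between 1.11% and 3.32% in every setting run. CLEC9A and CD1C were both above 0 in 0% of Blood and 0.671% of CB pre-cDC in the set. Blood pre-cDC formed 6 clusters at a resolution of 0.8 and 5 with 10 principal components, and CB pre-cDC in the set formed 2.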

Other observations

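The tests on lower MHC class II genes and on intermediate subset scores, the split of the cell line markers by type, and the settings that use the foreign-transcript set, were chosen only after their results were seen. The granule rule, the comparison by label number and the genes of the next 2 paragraphs were likewise picked after their values were known.

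Granule genes divided the CB pre-cDC. At least 3 of MPO, ELANE, PRTN3, CTSG and AZU1 were above 0 in 42.9% of 452 CB pre-cDC (interval 38.3% to 47.6%) and in 1 of 341 Blood pre-cDC (0.293%). Outside the foreign-transcript set 64.03% of CB pre-cDC met this rule (58.3% to 69.4%), and in the set 0 did, which allows up to 2.01%. Mature CD141+ cDC met it in 6 of 87 cells (6.90%, 2.57% to 14.4%) and CD1c+ cDC in 0 of 77, which allows up to 3.90%. By blocks of 50 label numbers, the shares of CB pre-cDC that met it were 88%, 44%, 24%, 44%, 84%, 100%, 4%, 0% and 0%. The receptor CSF1R went the same way, above 0 in 45.2% of CB pre-cDC outside the set and 6.71% in it, against 6.12% and 20% of Blood pre-cDC.

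Single genes of the AXL SIGLEC6 and pDC lists differed in their shares, although the AXL SIGLEC6 list as a whole had a median of 0.09 for pre-cDC against mature cDC both outside and in the set. AXL was above 0 in 94.3% of CD141+ cDC, 98.7% of CD1c+ cDC, 95.9% of Blood pre-cDC and 97.8% of CB pre-cDC. SIGLEC6 was at 0 in all 87 CD141+ cDC, which allows up to 3.45%, and above 0 in 5.19% of CD1c+ cDC, 13.5% of Blood pre-cDC and 5.31% of CB pre-cDC. For Blood pre-cDC that share was 11.7% outside the set and 15.9% in it, and for CB pre-cDC 5.94% and 4.03%. The antibody joining chain gene IGJ was above 0 in 1.53% of Blood pre-cDC outside the set and 77.2% in it, and in 8.91% and 87.2% of CB pre-cDC. PPP1R14A, also in the AXL SIGLEC6 list, went from 5.61% to 53.1% of Blood and from 12.9% to 65.1% of CB pre-cDC.

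The foreign transcripts included genes typical of several tissues and followed the label numbers. Above 0 in at least 25% of the set in both groups and in under 5% of other cells were 42 genes, and their mean levels in the Blood and CB sets had a Pearson correlation of 0.9799 across genes, which are not independent replicates. The correlation was partly built in, since the genes were picked for presence in both sets and some of them define the set. Related entries such as SNAR-A1 and SNAR-A3 counted apart, and SHANK2 had means near 0. The 42 genes included APOA2, above 0 in 99.3% of the Blood and 100% of the CB set, TFF1 (93.1% and 97.99%), DCT (94.5% and 97.3%) and the embryonic globin gene HBE1 (77.9% and 89.3%). They took 0.131% of the values in the Blood set and 0.353% in the CB set, by the median over cells. The 5% limit left out HBG1 and BCYRN1, which also rose in the set. BCYRN1 averaged 14.47 in the Blood and 14.95 in the CB set, against 3.19 and 2.24 outside it. The shares of the 42 genes are thus not those of all transcripts that rose in the set. From 1 label number upwards, 98.6% of Blood pre-cDC were in the set, and below that number none of them were. The same held for CB pre-cDC from another number upwards, with 99.3% of cells in the set from there on and none below.

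For these transcripts, RNA from liver cells alone was argued against, since the larger of the means of ALB (1.97 ± 2.61) and TTR (1.10 ± 2.33) lay at -7.82 from that of APOA2 (9.79 ± 1.49). A preference for short transcripts stays open. Of the short protein-coding genes near absent elsewhere, 9.91% appeared in the set. This was just inside the bound of 10% written in advance and far from the 50% such a preference was taken to need. However, genes near absent elsewhere may not be made in these cells at all, and a preference could not make those appear. Small RNA genes that rose in the set, such as BCYRN1, were outside this test, so it does not decide. RNA from a mixture of cell lines stays open. Of 35 marker genes of 6 line types, 15 (42.9%) appeared in the set, against 0 of 20 for other tissues, which met the bound written in advance. However, 14 of the 15 were among 20 markers of hepatocyte, melanoma and mammary lines, the tissues whose genes defined the set. The bound therefore does not decide, and the markers were split by line type. Of the markers of the other line types 1 of 15 appeared (6.67%, interval 0.169% to 31.9%), against 0 of 20 for other tissues, which is too few to decide, and MZB1 and DERL3 of the plasmacytoma list are also in the pDC list. A marker counted as appearing when above 0 in at least 5% of the set and in under 1% of all other cells. Markers that did not appear could thus still be above 0 in the set. Of the other line types, POU5F1 was so in 37.1% of the set and 15.7% of other cells. Of the other tissues, AGER was so in 31.6% and 7.99%. No label names such RNA or a batch, no biological explanation was tested, and how the transcripts reached these libraries stays open.

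Lower MHC class II genes in CB pre-cDC had a median difference of -1.79. In the foreign-transcript set granule gene cells were argued against, since no CB pre-cDC there met the granule rule and the median was -1.42. HLA-DRA averaged 12.713 in the CB cluster of 85 cells in the set and 10.002 in that of 64. CD74 averaged 11.864 and 10.352 in these clusters. The largest Blood cluster, with 95.9% of its cells in the set, had 13.315 and 11.632. For these genes the lower level in the set thus lay mainly in the cluster of 64 cells. That cluster also had more of some foreign transcripts. APOA2 averaged 11.36 there, 9.89 in the cluster of 85 and 8.74 in the Blood cluster, and HBG1 10.47, 8.57 and 7.35. BCYRN1 did not follow, at 14.76, 15.10 and 14.29. Whether the lower HLA-DRA and CD74 there go with the foreign transcripts was not tested. The list was not divided by cluster, so whether its lower median lay there too was not tested. Outside the set granule gene cells are a candidate explanation, since the median there was -0.45 without them and -3.04 in them. Among cells of the groups matched on detected genes the median was -2.00. The matching took no account of the set, which had more detected genes than other libraries in Blood and fewer in CB pre-cDC. Matched cells of the groups can thus differ in their shares of the set, so a difference in detected genes stays open outside and in it. Polymorphic HLA genes read against 1 reference were argued against as the whole source by -1.40 over the 14 list members outside them. The 10 members outside all HLA genes gave -0.88. The difference between cord blood and blood that the design names may underlie this pattern and is a hypothesis. Donors and batches cannot be told apart from the groups, because no label names them and each group counted as 1 sample.

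Intermediate subset scores of CB pre-cDC covered 34.7% of cells. A library of 2 cells from the CD141+ and CD1c+ ranges was argued against for most of these cells. Of them, 10 (6.37%, interval 3.10% to 11.4%) had both CLEC9A and FCER1A above 0. CLEC9A, a gene of the score, was above 0 in 88.9% of the 9 CB pre-cDC in the CD141+ range and in 12.7% of those between. Libraries of other pairs, such as those with a granule gene cell, were not tested. Fewer detected genes in the cells between the ranges were argued against, since their median was 101.5% of that in the CD1c+ range and 33.97% of CB pre-cDC with at least 2000 detected genes lay between the same bounds. Small RNA and unnamed entries in the score stay open, because 6.42% lay between without them, but so did 12.7% when all groups needed 2000 detected genes and the entries were kept, and both settings moved the CD1c+ bound, from -2.58 to -1.25 and -1.46. That bound rested on 2 of 39 CD1c+ cDC, with the next at -4.37. How many pre-cDC of either group are intermediate depends on it. Over cells, the CD141+ side of the score had a median of 1.89 in CB pre-cDC between the ranges and 1.90 in the CD1c+ range. The CD1c+ side had 3.91 and 6.06. The cells between thus had lower CD1c+ side genes rather than higher CD141+ side genes, and whether any are intermediate biologically stays open.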
